A study of Mus musculus with 23 samples.

How the data were processed

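Poly(A) RNA was measured in mouse germinal vesicle (GV) oocytes and preimplantation embryos labelled wild-type (WT) or Eif4enif1+/- (het). For embryos the labels do not say whether this is the genotype of the embryo or of its mother. GV oocytes were profiled by T&T-seq, which reads a transcriptome (total mRNA) and a translatome (ribosome-bound mRNA) from the same sample. Per the labels' protocols, ribosome-bound mRNA was captured with RiboLace, total mRNA came from direct lysis, both were reverse transcribed and amplified with a single-cell full-length mRNA kit, and sequencing libraries were made with a transposase-based kit (TruePrep). Embryo RNA-seq used the total-mRNA route. Neither molecular identifiers nor a strand-marking step is named in the labels, so amplified copies were counted as separate reads, and intervals and floors given with the values cover counting error only.

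The authors deposited 2 tables of raw read counts per gene, 1 for the 8 GV libraries and 1 for the 15 embryo libraries, each with 56196 genes. Trim Galore 0.6.4, HISAT2 2.1.0, featureCounts 1.6.5 and the mm10 build are named per the submitters' processing notes. The annotation release, the strand setting, the handling of reads that map to several places, and any removal of duplicate reads are not given in the sources used here. Genes that share sequence with a close copy (mitochondrial pseudogenes, vomeronasal receptors, the alpha-globin pair, the multicopy 2-cell-stage families) and genes that overlap a neighbour therefore have uncertain counts. In each of them 28 gene symbols had been turned into dates, as a spreadsheet does, and 27 of these were restored from the gene identifier. Of the 56196 identifiers, 54587 matched the reference name table with their version and 55154 without it. Every column had a sample. Coordinates and exon lengths are from a reference annotation on mm10.

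Groups were taken from the sample labels, with 2 libraries in each of the 4 GV groups and 3 in each of the 5 embryo groups. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may in part be technical. The sample descriptions give both fractions of a GV sample the same specimen number, so each translatome library has a transcriptome library from the same sample. This pairing entered only as an alternative fit. Deviations of paired libraries from their group means correlated across 9075 genes at 0.263 in het and 0.0578 in WT oocytes.

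Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 after the expression filter filterByExpr and TMM scaling, which left 22409 genes in GV oocytes and 23656 in embryos. All 8 GV libraries entered one model with 4 groups and all 15 embryo libraries one model with 5 groups, so that groups shared an estimate of the spread. No replicate term was included. Differences between fractions or between genotypes of a change were tested as interaction terms. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p under 0.05 were counted as called. Log2 fold changes are given with a standard error (SE) derived from the F statistic, and levels as TMM-scaled CPM (a gene's counts per M counts of its library), mean ± SD.

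For genes with no count in a group, the fold, or the difference of 2 changes, is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with its 95% exact counting interval.

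Comparisons, tests, the rule for named genes and 23 gene lists were fixed before the data were examined. The lists cover nuclear-encoded and mitochondrially encoded oxidative phosphorylation (OXPHOS) subunits, mitochondrial ribosomal proteins, mitochondrial fusion and fission, mitophagy, the TCA cycle, antioxidant genes, cytosolic ribosomal proteins, translation initiation, P-body and mRNA decay genes, oocyte and maternal-effect genes, meiotic cell cycle, 2-cell-stage genes, nucleolus, RNA polymerase II and splicing, stress and unfolded protein response (UPR), p53 and apoptosis, DNA methylation and chromatin, cytoskeleton, and markers of granulosa cells, sperm, blood and oviduct. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of members called over all genes and adjusted over the list alone are given beside it.

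The named genes are Eif4enif1, then in each comparison the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 10 CPM, groups that do not overlap (not asked of interactions) and a symbol that is not a predicted-gene, pseudogene or clone name. Where none passed, the 3 smallest p in each direction are given as values. From each list that passed, or had at least 3 called members, up to 4 called members with the smallest p are named, or 2 as values where none was called. A few genes that this rule names are not reported here.

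The position of each het embryo library between the WT 1-cell and WT 2-cell stages was computed over genes called in a fit of the 6 WT libraries alone with an absolute log2 fold change of at least 2. Group positions were compared by an exact two-sided permutation test, and for 3 libraries against 3 its p cannot go below 0.1.

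The edgeR and DESeq2 1.42.0 steps were tested on simulated data in which 200 genes were changed, 100 of them 2-fold and 100 of them 4-fold. In simulated GV translatomes of 22409 genes, edgeR recovered 8% of 2-fold and 65% of 4-fold changes with 5 false calls among 78, and DESeq2 18% and 68% with 25 false calls among 111. In simulated 1-cell embryos of 23656 genes, edgeR recovered 0% of both sizes and made 0 calls, and DESeq2 recovered 1% and 13% with 33 false calls among 47.

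Alternatives were median-ratio size factors (RLE) in place of TMM, no expression filter, mitochondrially encoded genes left out of the scaling, only the compared libraries in the fit, the replicate number as a block, the sample of both fractions as a block, the DESeq2 Wald test, a fold-change minimum, an estimated inter-gene correlation, and each library left out in turn. After the data were seen, fits without 2 het 1-cell libraries whose counts stop at a ceiling and fits without the arrested embryos were added. RLE in place of TMM shifted the median log2 fold change of all genes by 0.17 in the WT and 0.17 in the het 2-cell versus 1-cell comparison and by -0.13 in arrested versus 2-cell embryos, and by under 0.1 elsewhere. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.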

Results

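Samples labelled heterozygous for Eif4enif1 (Eif4enif1+/-, het) were compared with samples labelled WT in fully grown oocytes and over the earliest embryonic stages. Eif4enif1 encodes 4E-T, a protein that binds the cap-binding factor eIF4E and is a component of P-bodies, cytoplasmic granules of stored and decaying mRNA. GV oocytes are fully grown oocytes held in meiotic prophase, and they contributed 2 translatome and 2 transcriptome libraries per genotype. Embryo RNA-seq covered WT and het 1-cell embryos, WT and het 2-cell embryos cultured for 24 h, and het embryos that had stayed at 1 cell after 24 h of culture (arrested), with 3 libraries per group. The labels do not say whether the genotype of an embryo is its own or its mother's, so for embryos het and WT name the label alone.

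Total counts of the GV libraries were 38.74 M and 17.84 M in the WT translatome and 44.34 M and 45 M in the WT transcriptome. They were 50.49 M and 23.17 M in the het translatome and 3.62 M and 19.82 M in the het transcriptome. Embryo libraries held 18.32 M, 17.99 M and 21.69 M (WT 1-cell), 5.6 M, 13.43 M and 7.34 M (het 1-cell) and 31.58 M, 20.62 M and 40.38 M (WT 2-cell). Totals were 19.44 M, 31.89 M and 22.44 M in het 2-cell and 16.71 M, 19.16 M and 16.06 M in arrested libraries. In het 1-cell libraries 1 and 3 no gene exceeded 2220 and 2225 counts per kb of exon, against maxima between 203869 and 282174 in the other 4 1-cell libraries. The 100 most abundant genes held 6.34% and 5.53% of their counts, against 32.06% to 38.05%.

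Eif4enif1 itself (ENSMUSG00000020454.17, chromosome 11, 3202392 to 3244588, plus strand of mm10, 6370 bp of exon) was lower in het than in WT libraries at every stage measured. In GV oocytes it fell by 1.24 on the log2 scale in the translatome (SE 0.26, adjusted p = 0.0224), from 291 ± 29.8 CPM to 124 ± 37.3 CPM (SD, n = 2). In the transcriptome it fell by 1.26 (SE 0.26, adjusted p = 0.0283), from 219 ± 3.56 to 91.7 ± 6.24 CPM (n = 2). The difference between these changes was 0.02 (SE 0.37). In 1-cell embryos the level was 153 ± 22.4 CPM in WT and 70.4 ± 1.5 CPM in het libraries (n = 3, log2 -1.12, SE 0.41). It was 68.7 ± 11.6 and 45.3 ± 8.61 CPM in 2-cell embryos (n = 3, log2 -0.60, SE 0.41). Both comparisons had an adjusted p of 1. In each of these 4 pairs of groups every het library lay below every WT library. The structure of the mutant allele is not given in the sources used here, so whether counted reads come from both alleles is open, as is whose genotype the embryo labels give. Arrested embryos held 110, 28.5 and 62.7 CPM. Without het translatome library 2 or WT translatome library 1 the adjusted p of the translatome decrease was 0.198 and 0.0847, with only the 4 translatome libraries in the fit it was 0.0512 (log2 -1.26), and without any 1 of the transcriptome libraries that of the transcriptome decrease lay between 0.0526 and 0.237.

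**Figure D1:**
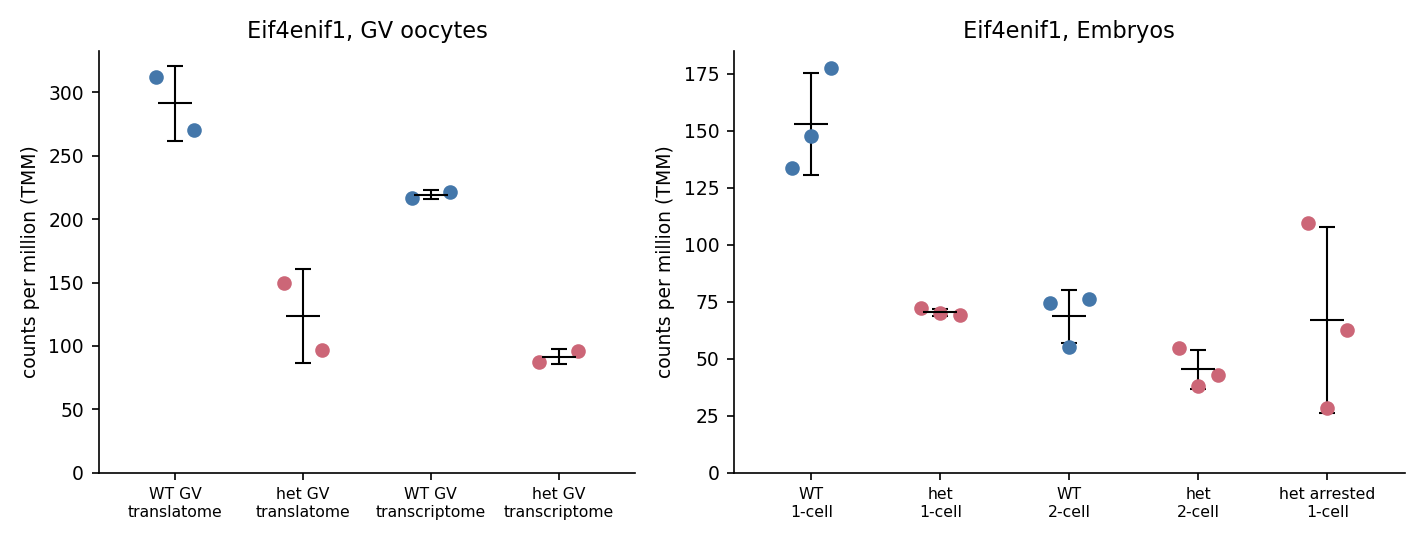
Eif4enif1 in each library, in TMM-scaled CPM (vertical axis), by group (horizontal axis), with GV oocytes on the left and embryos on the right. Points are libraries (blue WT, red het), bars means and whiskers 1 SD; het GV oocytes average 124 and 91.7 against 291 and 219 in WT.

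The first question was which mRNAs differ on ribosomes between het and WT oocytes. All 13 mitochondrially encoded OXPHOS mRNAs rose in the het translatome, with a median log2 change of 2.12. Among them were the cytochrome c oxidase subunits mt-Co1 (385 ± 33 to 1695 ± 310 CPM, log2 2.14, SE 0.29, n = 2), mt-Co2 (2.51) and mt-Co3 (135 ± 40 to 874 ± 263 CPM, log2 2.70, SE 0.34). The ATP synthase subunit mt-Atp6 rose as well (334 ± 36.9 to 2207 ± 1096 CPM, log2 2.72). Of 79 cytosolic ribosomal protein mRNAs 24 rose and 0 fell, including Rps27 (17.3 ± 3.97 to 67.2 ± 5.26 CPM, log2 1.95, SE 0.28), Rps28 (1.80), Rpl9 (1.79) and Rpl41 (1.70). Of 78 nuclear-encoded OXPHOS mRNAs 8 rose and 0 fell. Those with the smallest p were the ATP synthase subunits Atp5e (79.4 ± 4.02 to 238 ± 2.13 CPM, log2 1.58, SE 0.30) and Atp5j (1.42), the complex III subunit Uqcrq (1.2) and the complex I subunit Ndufc1 (1.29). Mitochondrial ribosomal proteins had 3 of 78 members higher, Mrpl54 (1.16), Mrpl58 (1.07) and Mrpl13 (1.05).

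Adjusted over the list alone, the numbers that rose were 13 of 13 mitochondrially encoded OXPHOS, 60 of 79 cytosolic ribosomal protein, 26 of 78 nuclear-encoded OXPHOS and 7 of 78 mitochondrial ribosomal protein mRNAs. Their medians were 2.12, 0.86, 0.70 and 0.35, with camera adjusted p of 1.17e-26, 2.32e-27, 1.41e-12 and 1.21e-04 at the preset correlation. None of these 4 list calls held with an estimated correlation (adjusted p = 0.279, 0.317, 0.497 and 0.483 with an estimated correlation, in that order). Beside them, mitochondrially encoded genes took 0.66% and 1.32% of counts in het and 0.23% and 0.16% in WT translatome libraries. Markers of granulosa cells, the somatic cells that surround the oocyte, summed to 1159 and 1572 CPM in het and 582 and 853 CPM in WT translatome libraries. Of 23 markers 5 rose (8 adjusted over the list alone), and the activin antagonist Fst (2.27), the anti-Müllerian hormone receptor Amhr2 (1.73), the matrix proteoglycan Vcan (2.71) and the nuclear receptor Nr5a2 (1.03) had the smallest p. The granulosa list had a median of 1.03 (adjusted p = 1.55e-05, and adjusted p = 0.372 with an estimated correlation).

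Stress and antioxidant genes also moved. Nupr1, a stress-induced chromatin regulator, rose from 10.2 ± 0.514 to 86.6 ± 14.9 CPM (log2 3.09, SE 0.28, adjusted p = 2.85e-04), Xbp1, a UPR transcription factor, by 2.36, and Psph, of serine synthesis, by 1.95. The stress and UPR list had 5 of 39 members up and 1 down (7 and 1 adjusted over the list alone), a median of 0.23 and an adjusted p of 0.0218, and an adjusted p = 0.573 with an estimated correlation. The glutathione-synthesis subunit Gclc (3.08, SE 0.46), the sulfiredoxin Srxn1 (3.23) and the glutathione peroxidase Gpx1 (1.04) rose while the thioredoxin reductase Txnrd1 fell (-1.25). These were the 4 called of 27 antioxidant genes (5 up and 1 down adjusted over the list alone, median 0.50). The antioxidant list had an adjusted p of 0.00101, and adjusted p = 0.279 with an estimated correlation. The largest increases by rule were Cebpb, a C/EBP transcription factor (0.737 ± 0.589 to 47.7 ± 3.84 CPM, log2 5.84, SE 0.74), Ier5l (4.06) and the cell-cycle regulator Rgcc (3.79). Next came the cardiolipin synthase Crls1 (1.94 ± 0.875 to 24.5 ± 0.524 CPM, log2 3.71, SE 0.42), Slc7a4 (3.68) and the cold-shock RNA-binding protein Ybx3 (15.2 ± 0.0941 to 170 ± 11.7 CPM, log2 3.49, SE 0.45).

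Lower in the het translatome were Kit, the receptor for the granulosa-derived Kit ligand (222 ± 75.2 to 69.8 ± 18.8 CPM, log2 -1.67), Zbed3 (-1.59) and Nlrp9b (-1.28), while Dppa5a rose (1.54). These were the called members of 47 oocyte and maternal-effect genes, with 1 up and 3 down also adjusted over the list alone (median -0.31, list adjusted p = 0.0132, and adjusted p = 0.623 with an estimated correlation). Of 60 meiotic cell-cycle genes, the centriole-duplication kinase Plk4 (-1.23) and the spindle-checkpoint gene Mad1l1 (-1.04) fell (5 adjusted over the list alone, median -0.27, list adjusted p = 0.00102, and adjusted p = 0.462 with an estimated correlation). P-body and mRNA decay genes went both ways, with 3 up and 3 down of 49 (7 and 4 adjusted over the list alone). The uridylyltransferase Tut4 (2.73), the P-body component Lsm14b (2.05) and the decapping activator Lsm1 (1.07) rose and the deadenylase subunit Pan2 fell (-1.33), and the list did not pass (adjusted p = 0.805). The largest decreases by rule were Cyp2c29 (28.8 ± 2.44 to 4.27 ± 1.28 CPM, log2 -2.76, SE 0.32), the mucin Muc20 (-2.74), the vomeronasal receptors Vmn1r157 (-2.67), Vmn1r112 (-2.67) and Vmn1r132 (-2.46), whose close copies can share reads, and Rflnb (-2.29).

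In the remaining lists, mitochondrial fusion and fission had 0 up and 1 down of 30, the TCA cycle 0 of 28, mitophagy 0 of 30, translation initiation 2 up of 43, and 2-cell-stage genes 2 up and 1 down of 30 with Dppa4 at -1.90. The nucleolus list had 1 up and 1 down of 48, RNA polymerase II and splicing 1 and 1 of 52, p53 and apoptosis 2 up of 36, and cytoskeleton 1 and 1 of 42. DNA methylation and chromatin genes had 2 up and 1 down of 50, including the demethylase Kdm1a (1.74) and the imprinting factor Zfp57 (511 ± 113 to 174 ± 41 CPM, log2 -1.56). Of the other-cell markers, sperm had 1 of 7 up, blood 0 of 8 and oviduct 0 up and 1 down of 11. None of these 13 lists passed the list test. In total 1034 of 22409 genes were called, 584 up and 450 down. The count depended on single libraries, with 154, 206 and 403 calls without het translatome 1, het translatome 2 or WT translatome 1. Without the expression filter it was 2113, and DESeq2 called 1860. The oocyte list failed without het translatome 2 (median -0.20, adjusted p = 0.505) or WT translatome 2 (0.10, 0.980) and stood at -0.51 without het translatome 1. The stress list failed without het translatome 1 (0.15, 0.0960) or WT translatome 1 (0.062, 0.424) and stood at 0.44 without WT translatome 2. Without WT translatome 1 the medians of nuclear-encoded OXPHOS and antioxidant genes were 0.38 and 0.31.

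The transcriptome libraries asked the same question of total mRNA. Of the 13 mitochondrially encoded OXPHOS mRNAs 5 rose (13 adjusted over the list alone, median 1.29), with mt-Nd1 (157 ± 9.63 to 458 ± 131 CPM, log2 1.55), mt-Nd6 (1.82), mt-Nd5 (1.27) and mt-Co1 (1.21) at the smallest p. This list had an adjusted p of 1.75e-13, and adjusted p = 0.362 with an estimated correlation. Cytosolic ribosomal proteins had 4 of 79 up, Rpl9 (1.87), Rps23 (1.23), Rps27 (1.19) and Rps3a1 (1.12), 8 adjusted over the list alone (median 0.49). Its adjusted p was 4.36e-12, and adjusted p = 0.443 with an estimated correlation. P-body and mRNA decay genes had 3 of 49 up, Tut4 (2.63) and the mRNA-destabilising factors Zfp36l2 (2.01) and Tob1 (1.67), 6 adjusted over the list alone (median 0.45). Their list had an adjusted p of 0.00332, and adjusted p = 0.362 with an estimated correlation. Nuclear-encoded OXPHOS and mitochondrial ribosomal proteins had 0 of 78 called each in edgeR (list adjusted p = 0.120 and 0.774).

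Gclc (2.52), the peroxiredoxin Prdx4 (1.74), the glutathione-synthesis modifier subunit Gclm (1.28) and Srxn1 (14 counts against 0, at least 16.4-fold higher) rose among 27 antioxidant genes, with 4 up and 1 down adjusted over the list alone (median 0.30). For these genes the list adjusted p was 0.035, and adjusted p = 0.362 with an estimated correlation. Among stress and UPR genes Nupr1 (4.69 ± 0.447 to 62.5 ± 15.9 CPM, log2 3.73, SE 0.29, adjusted p = 1.58e-04), Xbp1 (2.75), Cebpb (3.82) and the cystathionine lyase Cth (1.36) rose. They were the 4 called of 39 (5 up and 3 down adjusted over the list alone), and the list missed its threshold (adjusted p = 0.0804). The DNA methylation and chromatin list had 0 of 50 called in edgeR (3 up and 1 down adjusted over the list alone, median 0.32). It had an adjusted p of 0.00332, and adjusted p = 0.443 with an estimated correlation. Rgcc (5.59 ± 1.33 to 101 ± 0.772 CPM, log2 4.17, SE 0.35), the long noncoding RNA Malat1 (3.23, SE 0.38), the glutathione transferase Gstm2 (2.79) and the lysosomal protease Ctsl (24.3 ± 12.5 to 164 ± 17 CPM, log2 2.76) completed the 6 largest increases. The largest decreases were Muc20 (-3.03), its chromosomal neighbour Muc4 (-2.70, SE 0.32), Cyp2c29 (-2.68), Vmn1r157 (-2.50), Vmn1r112 (-2.47) and Vmn1r132 (-2.36). Malat1 lies beside Gm37376, also called higher, and neighbours may share reads.

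Granulosa markers had 5 of 23 up in the transcriptome (10 adjusted over the list alone), including Fst (3.61), the natriuretic peptide receptor Npr2 (3.86), Vcan (4.31) and Hsd3b1 (2.15), with a median of 1.2. The marker list had an adjusted p of 5.44e-08, and adjusted p = 0.362 with an estimated correlation. The marker sums were 775 and 568 CPM in het and 387 and 627 CPM in WT transcriptome libraries, which overlap, while the mitochondrial share was 0.68% and 1.0% in het against 0.31% in each WT library. Het transcriptome library 1, with 3.62 M counts, was the shallowest of the 8. In total 572 of 22409 genes were called, 317 up and 255 down. Without het transcriptome 1, het transcriptome 2 or WT transcriptome 2 the count was 202, 69 and 207, without the filter 1554, and by DESeq2 1423. The antioxidant list failed without het transcriptome 1 or WT transcriptome 1 or with only these 4 libraries in the fit (adjusted p = 0.0778, 0.105 and 0.0503). The DNA methylation list failed without WT transcriptome 2 (median 0.13, adjusted p = 0.118) and stood at 0.53 without WT transcriptome 1, and the P-body median was 0.27 without het transcriptome 2. Scaling by RLE gave 65.7% of calls up against 55.4%.

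**Figure D2:**
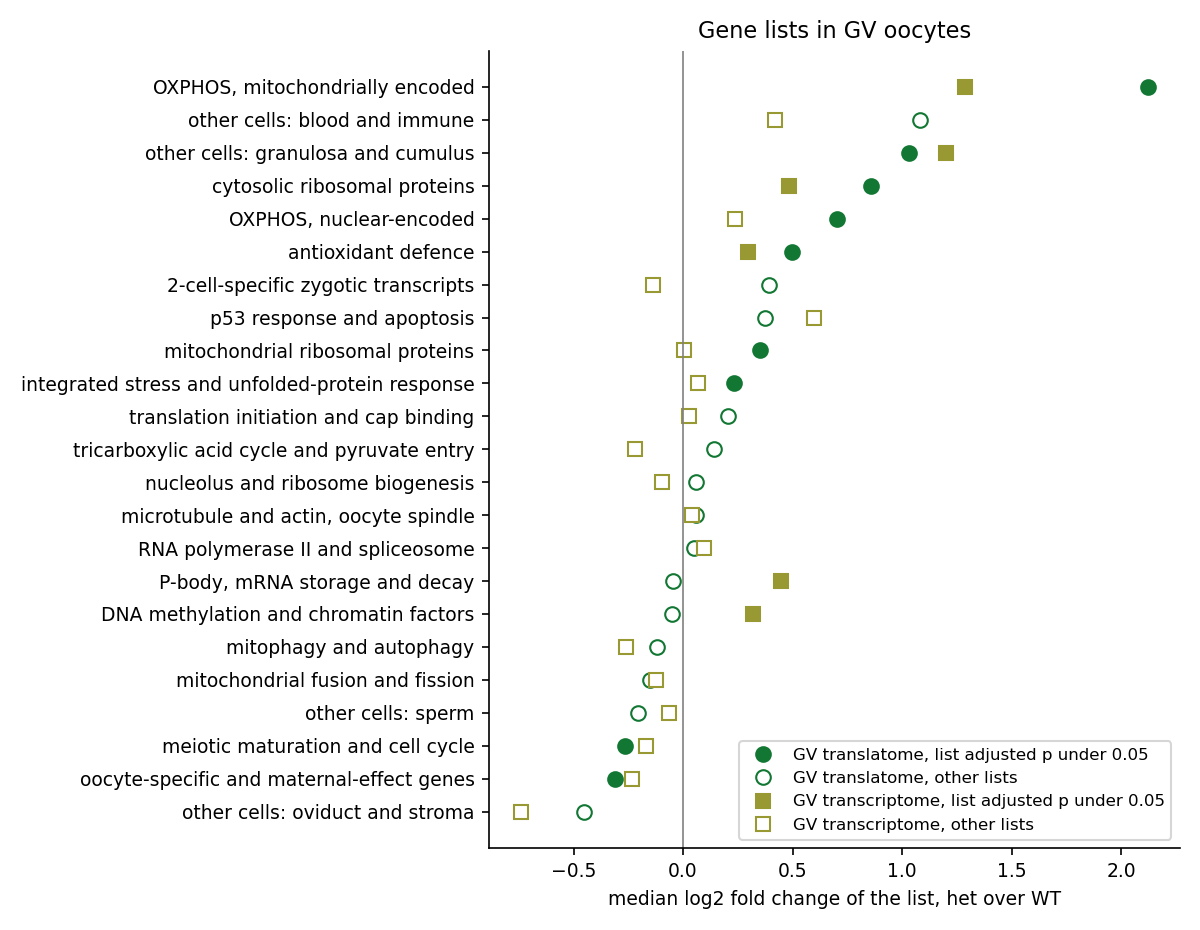
Median log2 fold change, het over WT (horizontal axis), of each fixed gene list (vertical axis) in the GV translatome (circles) and transcriptome (squares). Filled symbols passed the list test at the preset correlation, and mitochondrially encoded OXPHOS genes lie farthest to the right in the translatome at 2.12 and at 1.29 in the transcriptome.

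Whether genotype changed translatome levels beyond mRNA level was tested as the difference between the translatome and transcriptome changes. Mtfr2, a mitochondrial fission regulator (chromosome 10, 20347770 to 20361304), was the named gene that passed. It fell by 1.88 in the translatome (adjusted p = 0.0026), with 10.1 and 10.6 CPM in het against 35.5 and 40.9 CPM in WT libraries. In the transcriptome it stood at 0.77 (adjusted p = 0.0971), with 108 and 103 CPM in het against 57.6 and 66.5 CPM in WT. The difference was -2.65 (SE 0.34, adjusted p = 0.0254). The other 2 called genes lie outside the naming rule and were chosen after their values were seen. Mycl, a MYC-family transcription factor, had a difference of -3.77 (SE 0.50, adjusted p = 0.0254). It had 6.11 and 8.14 CPM in het against 10.7 and 10.7 CPM in WT translatome libraries and 5.75 and 5.24 against 0.632 and 0.559 CPM in the transcriptome. The predicted gene Gm21887 had a difference of 3.52 (SE 0.47), with 62.1 and 63.7 against 11.4 and 9.60 CPM in the translatome and 3.75 and 5.62 against 12.1 and 6.73 CPM in the transcriptome.

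At the preset correlation 7 lists shifted between fractions. Upward in the translatome relative to the transcriptome were nuclear-encoded OXPHOS (median 0.52, adjusted p = 7.36e-07), mitochondrially encoded OXPHOS (0.84, 1.59e-04), mitochondrial ribosomal proteins (0.37, 4.55e-05), cytosolic ribosomal proteins (0.36, 1.11e-04) and the TCA cycle (0.38, 0.0373). Downward were P-body genes (-0.25, 6.59e-04) and DNA methylation genes (-0.35, 0.00373). All 7 had an adjusted p = 0.805 with an estimated correlation. In edgeR these lists had 0 called members over all genes, of 1999 genes with an unadjusted p under 0.05, and adjusted over the list alone only 4 mitochondrially encoded genes up and 1 P-body gene down. Values with the smallest p include mt-Co3 1.41, Ndufv1 1.24, Idh3g of the TCA cycle 1.31, the mRNA-binding protein Ybx1 -2.08 and Dnmt1 -1.30. With each oocyte sample as a block, 7 genes were called in place of 3. Without any 1 het library or WT transcriptome 1 the count was 0. Without WT translatome 1 it was 10, without the filter 108, and by DESeq2 112. Nuclear-encoded OXPHOS failed without WT translatome 1 (median 0.25, adjusted p = 0.225) and had medians of 0.33 and 0.92 without het translatome 1 and WT translatome 2. Mitochondrially encoded OXPHOS failed without het translatome 2 or het transcriptome 1 (0.28 and 0.46, adjusted p = 0.126 and 0.0652). Cytosolic ribosomal proteins failed without het transcriptome 1 (0.22, adjusted p = 0.132) and had 0.54 and 0.56 without het transcriptome 2 and WT translatome 2. DNA methylation genes failed without het translatome 2 or WT transcriptome 2 (-0.28 and -0.19, adjusted p = 0.0637 and 0.244) and had -0.21 without WT translatome 2, and the P-body median was -0.38 without WT transcriptome 1. The TCA cycle list failed with RLE scaling (adjusted p = 0.0644) or without het translatome 1, het transcriptome 2, WT translatome 1 or WT transcriptome 2 (0.399, 0.226, 0.519 and 0.186).

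**Figure D3:**
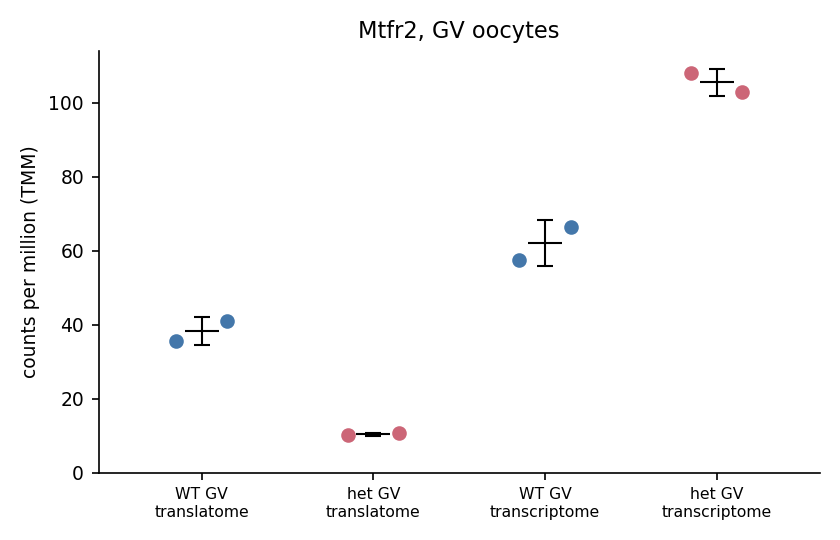
Mtfr2 in the 8 GV libraries in TMM-scaled CPM (vertical axis), by genotype and fraction (horizontal axis), with points for libraries, bars for means and whiskers for 1 SD (n = 2). Het libraries lie at 10.1 and 10.6 against 35.5 and 40.9 in the translatome, and at 108 and 103 against 57.6 and 66.5 in the transcriptome.

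WT oocytes alone show which mRNAs were enriched on ribosomes at this stage. Maternal-effect and fertilisation genes were among those higher in the translatome. Astl, the protease of the zona block (log2 2.93), Nlrp5, of the subcortical maternal complex (2.41), the zona protein Zp2 (1.85) and Kit (1.49) were the leading 4 of 7 called of 47, with 0 lower (8 adjusted over the list alone). The list median was -0.10 while its mean was 0.29, and the list did not pass (adjusted p = 0.390). The mitofusins Mfn1 (1.17) and Mfn2 (1.51), the maintenance methyltransferase Dnmt1 (1.75) and its partner Uhrf1 (1.93), and the chaperone Hspa5 (2.53) were also higher. Meiotic genes had 13 of 60 up, with the cyclin Ccnd2 (3.93) and Incenp of the chromosomal passenger complex (1.73), stress and UPR genes 10 up and 1 down of 39, and cytoskeletal genes 9 up and 2 down of 42. Adjusted over the list alone, the 3 lists had 18 up and 3 down, 13 and 2, and 11 and 2. Their medians were 0.39, 0.36 and 0.37 and their adjusted p 0.00745, 0.0172 and 0.0188, and adjusted p = 0.497, 0.501 and 0.497 with an estimated correlation. Granulosa markers had 7 of 23 up (8 adjusted over the list alone, median 0.83, list adjusted p = 0.00251, and adjusted p = 0.497 with an estimated correlation).

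Lower in the translatome were 51 of 79 cytosolic ribosomal proteins (65 adjusted over the list alone, median -0.97), with Rpl41 (-1.88) and Rps28 (-1.88), and 31 of 78 mitochondrial ribosomal proteins (49, median -0.74). So were 28 of 78 nuclear-encoded OXPHOS genes with 2 higher (39 and 2, median -0.83), with Atp5e (-2.18), and 3 of 13 mitochondrially encoded OXPHOS genes (5, median -0.73). Their adjusted p were 4.43e-24, 2.63e-15, 5.58e-14 and 0.00251, and adjusted p = 0.497, 0.490, 0.501 and 0.594 with an estimated correlation. The largest increases were Lmbr1l (2.40 ± 0.428 to 61.3 ± 12.2 CPM, log2 4.67, SE 0.31, adjusted p = 2.08e-05), Tspan18 (4.49), Mafk (4.44), Synpo (4.40), the actin crosslinker Flna (4.10) and Fstl1 (4.08). The largest decreases were the noncoding Rn7s6 (-2.67), Arl5c (-2.61), the deadenylase subunit Pan3 (-2.45), Rps12 (-2.40), Tsc22d1 (1020 ± 40.4 to 201 ± 47.9 CPM, log2 -2.35) and Ociad1 (-2.29), and Eif4enif1 stood at 0.41 (adjusted p = 0.3). Across 22381 genes the log2 difference between fractions had a Spearman correlation of 0.357 with exon length, genes not being independent replicates. In total 3269 genes were called, 2006 up and 1263 down, and with only the 4 WT libraries in the fit 1570, of which 72.7% were up against 61.4%. Without WT translatome 1, WT transcriptome 1 or WT transcriptome 2 the count was 1992, 1195 and 1850. Without WT translatome 2 the meiotic, stress and cytoskeletal lists did not pass (adjusted p = 0.0680, 0.124 and 0.116), nor did the cytoskeletal list without WT transcriptome 2 (0.0877). The stress median lay between 0.20 and 0.61 with any 1 of the 4 libraries left out, and without WT translatome 1 the granulosa and nuclear-encoded OXPHOS medians were 0.43 and -0.54.

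In 1-cell embryos, where transcription from the new genome has barely begun and most mRNA is maternal, edgeR called 0 of 23656 genes between het and WT (889 had an unadjusted p under 0.05), and DESeq2 called 83. The 3 genes with the smallest p in each direction are given as values, the dynein regulatory subunit Drc1 1.75 (SE 0.43), Nt5c3 1.70 and Ttll13 1.49 on the higher side. On the lower side were Pdpn -2.19 (SE 0.49, 15.7 ± 0.846 CPM in het and 71.5 ± 29.5 CPM in WT, n = 3), Tex30 -1.52 and Fbxw13 -1.71, all with an adjusted p of 1. Oocyte and maternal-effect genes had a median of -0.87 (adjusted p = 2.23e-15), with the oocyte growth factor Gdf9 at -1.78 (789 ± 973 against 2705 ± 925 CPM) and Kit at -0.92. Mitochondrially encoded OXPHOS genes had a median of -0.98 (adjusted p = 6.17e-15), with mt-Nd6 at -1.28 and mt-Nd5 at -1.07. Both had an adjusted p = 0.257 with an estimated correlation. Without het 1-cell library 1, 2 or 3 the oocyte median was -0.57, -1.62 and -0.54 and the mitochondrially encoded median -0.52, -3.10 and -0.49.

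Smaller shifts passed for RNA polymerase II and splicing (median -0.21, adjusted p = 5.9e-05), DNA methylation (-0.17, 0.00237), nuclear-encoded OXPHOS (-0.11, 0.0148) and P-body genes (-0.06, 0.0283), and had adjusted p = 0.318, 0.257, 0.677 and 0.562 with an estimated correlation. No member of these 6 lists was called by edgeR, over all genes or adjusted over the list alone. The mitochondrial share was 0.44%, 3.68% and 0.34% in het libraries 1, 2 and 3, the first and last being those with the count ceiling, against 2.58%, 2.39% and 2.35% in WT. Without the 2 ceiling libraries, an alternative chosen after seeing the data, the medians of oocyte, mitochondrially encoded and nuclear-encoded OXPHOS genes were 0.15, 0.25 and -0.0029 (adjusted p = 0.907, 0.0605 and 0.907), and the other 3 lists did not pass either (0.907, 0.907 and 0.911). The nuclear-encoded OXPHOS list failed without WT library 1 (median 0.095, adjusted p = 0.214) or het library 3 (-0.16, 0.0986) or with only these 6 libraries in the fit (-0.18, 0.0721), and its medians were -0.072 and -0.20 without het library 1 and WT library 3. P-body genes failed without het library 3 (-0.13, 0.0986) or WT library 3 (0.0019, 0.252) or with only these 6 libraries (-0.14, 0.255), and had -0.18, -0.29 and -0.0089 without het library 1, WT library 1 and WT library 2. DNA methylation genes failed with only these 6 libraries (adjusted p = 0.0633) and had 0.028 and -0.29 without WT libraries 3 and 2, and RNA polymerase II genes had -0.40 without WT library 1. Without het library 2, which has no ceiling, 284 genes were called.

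For 2-cell embryos, the stage of the major zygotic genome activation in mouse, edgeR called 1 of 23656 genes and DESeq2 140. The 1 gene, Btg1-ps1, is a pseudogene outside the naming rule and was chosen after its values were seen; it had 0 counts in the 3 WT libraries and 30, 64 and 47 counts in the het libraries (adjusted p = 0.00286). With only these 6 libraries in the fit edgeR called 0 genes, and another split of the 6 also gave 1 call. It called 2 genes without WT library 3, het library 1 or the filter, and 4 without the arrested embryos. Values with the smallest p were Max, the MYC partner, 1.70, Ceacam10 1.61 and Prl8a2 2.04. In the other direction they were Abhd18 -1.89 (27.8 ± 2.38 CPM in WT and 7.52 ± 2.03 CPM in het, n = 3, adjusted p = 0.440), Trim12a -5.05 and Muc4 -1.79. The 2-cell-stage genes had a median of 0.71 (adjusted p = 0.00295), with Tcstv3 at 1.25 and Gm6763 at 2.01. Oocyte genes had 0.52 (0.00295), with Zp1 at 1.04 and the oocyte transcription factor Nobox at 1.77, and mitochondrially encoded OXPHOS genes 0.69 (0.0071).

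Cytosolic ribosomal proteins (-0.10, adjusted p = 0.0470), nucleolus (-0.17, 0.0373) and RNA polymerase II genes (-0.17, 0.0224) leaned the other way in 2-cell embryos. All 6 lists had an adjusted p = 0.820 with an estimated correlation, and edgeR called 0 members over all genes or adjusted over the list alone (1318 genes had an unadjusted p under 0.05). The ribosomal protein and nucleolus medians had the opposite sign without het 2-cell library 1, at 0.29 and 0.047 (adjusted p = 0.00239 and 0.897), and RNA polymerase II, oocyte and 2-cell-stage genes failed without it (0.031, 0.14 and 0.20, adjusted p = 0.989, 0.349 and 0.0527). Without WT 2-cell library 1 ribosomal proteins (0.0048, 0.479), nucleolus (-0.11, 0.450), RNA polymerase II (-0.15, 0.295) and oocyte genes (0.40, 0.0563) did not pass, and without het 2-cell library 2 mitochondrially encoded genes did not (0.34, 0.214). Ribosomal proteins also failed without WT 2-cell library 2, with only these 6 libraries or with RLE scaling (adjusted p = 0.143, 0.0994 and 0.0557). Their median ran from -0.49 to 0.29 with each library left out, and was -0.25 with the replicate number as a block. Without het 2-cell library 3 the nucleolus and RNA polymerase II medians were -0.43 and -0.49, and without WT library 3 the oocyte median was 0.83. Mitochondrially encoded genes took 15.9% ± 3.35 of counts in het and 9.80% ± 0.514 in WT 2-cell libraries (n = 3), with every het library above every WT library. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows.

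**Figure D4:**
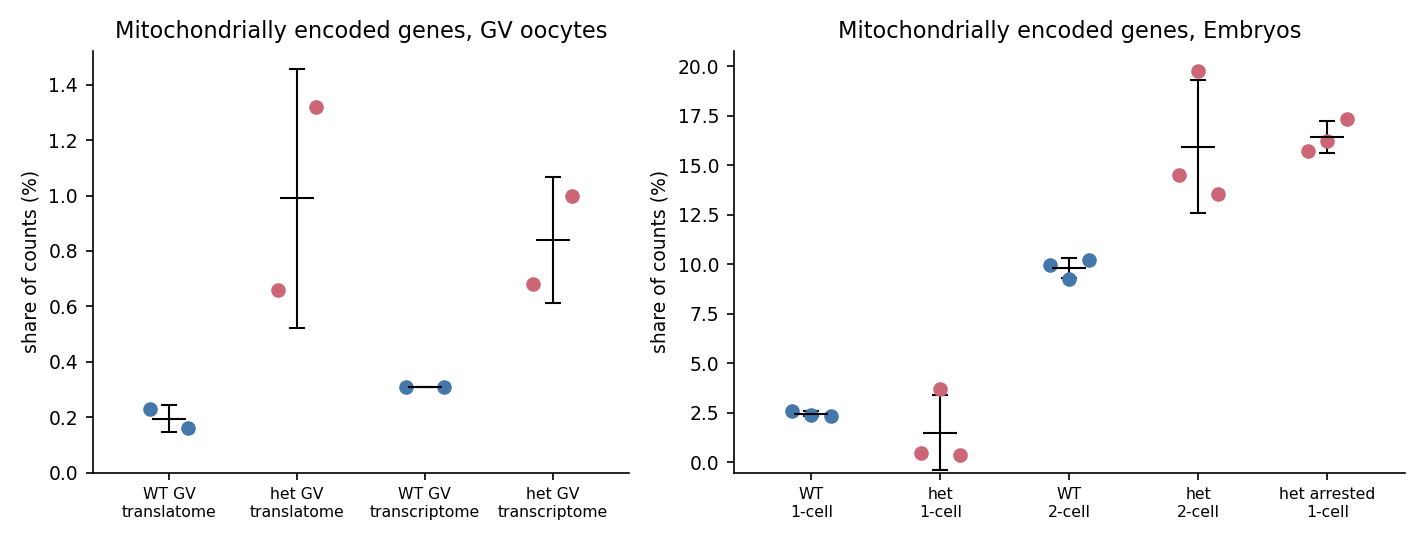
Share of counts from mitochondrially encoded genes in percent (vertical axis), by group (horizontal axis), in GV oocytes (left) and embryos (right). Points are libraries (blue WT, red het), bars means and whiskers 1 SD; het GV libraries lie between 0.66% and 1.32% against 0.16% to 0.31% in WT, and het 1-cell libraries 1 and 3 lie at 0.44% and 0.34%.

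Between the WT 1-cell and 2-cell stages poly(A) mRNA levels changed on a large scale. Tail length and total mRNA were not measured. Ribosomal protein mRNAs rose in 74 of 79 cases (76 adjusted over the list alone, median log2 4.71), with Rpsa (7.73), Rps23 (6.77) and Rpl8 (4.81). Of 48 2-cell-stage genes 42 rose and 1 fell (43 and 1 adjusted over the list alone). The median was 6.71, or 6.45 with the 10 genes without WT 1-cell counts at their bound. The ratios of leading members rested on few 1-cell counts, with Gm8300 at 851 to 25405 (2 counts) and Gm2016 at 4288 to 943808 (1 count). Crxos, a homeobox gene, was at least 13954-fold higher (859 ± 143 CPM against 0 counts, n = 3). Next, as bounds, came the mitochondrial import subunit Tomm5 (10874-fold), the homeobox gene Obox8 (10097-fold), Pdxk (9373-fold) and Prdx4 (5421-fold). Selenos, with 1 count in WT 1-cell embryos, had a ratio between 12093 and 2661314. Nucleolar genes had 28 up and 1 down of 48 (31 and 2 adjusted over the list alone, median 1.89), with Nop16 (11.72).

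Oocyte and maternal-effect genes had 35 of 47 down and 3 up (35 and 3 adjusted over the list alone, median -3.43), with the meiotic kinase Mos (-6.54), Nlrp9b (-5.14) and Nlrp5 (-3.43). P-body genes had 20 down and 6 up of 50 (20 and 6 adjusted over the list alone, median -0.69), with the maternal mRNA-binding protein Zar1 (-6.58) and the decapping cofactor Dcp1a (-4.23). DNA methylation genes had 19 down and 9 up of 50 (20 and 10 adjusted over the list alone, median -0.52), with Dnmt1 (-3.96) and Uhrf1 (-3.78). The largest decreases were Satl1 (-8.82), Cldn8 (-8.72), Lurap1l (-7.71), the oocyte linker histone H1foo (6403 ± 611 to 33.3 ± 16.6 CPM, log2 -7.59), Fam90a1a (-7.55) and Sbk3 (-7.37), and Eif4enif1 fell by 1.16 (adjusted p = 0.0329). Nuclear-encoded OXPHOS genes had 39 up and 6 down of 78 (39 and 6 adjusted over the list alone, median 1.35). Mitochondrially encoded ones had 5 of 13 up (5, median 1.71) and mitochondrial ribosomal proteins 39 up and 11 down of 78 (41 and 12, median 1.39).

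List adjusted p for this WT change were 1.68e-26 (ribosomal proteins), 1.74e-16 (2-cell-stage genes), 5.04e-13 (oocyte), 7.63e-05 (nucleolus), 0.0024 (nuclear-encoded OXPHOS), 0.00317 (P-body), and 0.0380 for mitochondrially encoded OXPHOS, mitochondrial ribosomal proteins, DNA methylation and blood markers. With an estimated correlation the adjusted p = 0.599 for nuclear-encoded OXPHOS, 0.689 for mitochondrially encoded OXPHOS, 0.640 for mitochondrial ribosomal proteins and 0.537 for the other 7. Of 9 blood markers 7 rose (7 up and 1 down adjusted over the list alone, median 9.38, or 6.25 at the bounds). They include the alpha-globins Hba-a1 (223 ± 45.7 CPM, ratio 1481 to 44182 on 2 counts) and Hba-a2, whose reads can be shared, and Cd74 (at least 1226-fold). The blood list failed without any 1 of the 6 WT libraries (adjusted p between 0.0783 and 0.102). Mitochondrially encoded OXPHOS failed without WT 1-cell library 1, WT 2-cell library 1 or the arrested embryos (0.0612, 0.0508 and 0.234), and mitochondrial ribosomal proteins without WT 1-cell library 3 or WT 2-cell library 1 or with only the WT libraries (0.0681, 0.0534 and 0.0684). DNA methylation genes failed without WT 1-cell library 3, WT 2-cell library 2 or 3 or the arrested embryos, with only the WT libraries, or with RLE scaling (0.0581 to 0.0694, median -0.33 under RLE). In total 10981 genes were called, 6735 up and 4246 down.

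Het embryos went through the same transition with 5398 genes up and 3295 down, 8693 in total. Ribosomal proteins rose in 77 of 79 cases (78 adjusted over the list alone, median 4.26), with Rpsa (6.33) and Rps23 (5.85), and 2-cell-stage genes in 43 of 48 (46, median 6.56, or 6.32 at the bounds). Mitochondrially encoded OXPHOS genes had 11 of 13 up (13, median 3.66), with mt-Nd3 (3.24) and mt-Nd4l (3.84). Their 1-cell share of counts was 0.44% and 0.34% in the 2 ceiling libraries and 3.68% in the other, and the median was 2.21 (adjusted p = 1.28e-06) without the ceiling libraries, a fit chosen after seeing the data, and 5.79 without the other. Oocyte genes had 26 down and 3 up of 47 (28 and 3, median -1.91, and -0.84 without het 1-cell library 2), with Mos (-5.56) and Nlrp9b (-4.32). Nuclear-encoded OXPHOS genes had 38 up and 4 down of 78 (40 and 4, median 1.57). Nucleolar genes had 23 of 48 up (26 up and 1 down, median 1.38), mitochondrial ribosomal proteins 31 up and 6 down (33 and 7, median 1.09) and translation initiation 20 up and 4 down of 43 (20 and 5, median 1.08). P-body genes had 6 up and 15 down (6 and 15, median -0.44), and blood markers 6 of 9 up (7 up and 1 down, median 7.46, or 6.22 at the bounds).

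The adjusted p of these lists in het embryos were 9.91e-29, 1.46e-23, 3.33e-08, 1.12e-05, 7.18e-05, 2.45e-04, 0.0285, 0.0278, 0.0278 and 0.0278 in the order given. With an estimated correlation the adjusted p = 0.588 for mitochondrial ribosomal proteins and 0.516 for the other 9. The homeobox gene Obox6 was at least 11553-fold higher (906 ± 547 CPM, n = 3, against 0 counts), Trim43a at least 9774-fold, Crxos at least 8442-fold, Pdxk at least 6649-fold and Rab20 at least 4017-fold. Timd2, with 1 count at the 1-cell stage, had a ratio between 7888 and 1736038. Zc4h2 was at least 641-fold lower, and the other largest decreases were the aromatase gene Cyp19a1 (-9.51), Sgo2b (-8.04), Gpatch1 (-7.22), Gulp1 (-6.94) and Npffr2 (-6.92). Eif4enif1 stood at -0.63 (adjusted p = 0.229). Without the 2 ceiling libraries 2017 genes were called, 855 up and 1162 down. Mitochondrial ribosomal proteins and translation initiation then no longer passed (list adjusted p = 0.171 and 0.307). The former also failed without het 2-cell library 2 or 3 (0.103 and 0.0876), and the latter without het 2-cell library 3 or with only the het 1-cell and 2-cell libraries (0.0767 and 0.0764). P-body genes failed without het 1-cell library 2 or the arrested embryos or with only the compared libraries (0.0572, 0.0514 and 0.0789) and had a median of -0.26 with RLE scaling. Blood markers failed without het 1-cell library 2 or any 1 of the het 2-cell libraries (0.0550 to 0.0695).

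Whether the transition differed between genotypes was tested as the het minus WT difference of the 2-cell versus 1-cell changes. In edgeR 1 gene was called, Btg1-ps1 (adjusted p = 0.0105), of 1049 with an unadjusted p under 0.05, and DESeq2 called 79. With 0 counts in WT 2-cell embryos its difference is a bound, at least 6.54 on the log2 scale. Mitochondrially encoded OXPHOS genes had a median difference of 1.70 (adjusted p = 3.25e-14), with mt-Nd6 at 1.70, and oocyte genes 1.22 (2.71e-15), with Gdf9 at 3.02 and Nlrp9a at 2.69, both with an adjusted p = 0.398 with an estimated correlation. Without the 2 ceiling libraries neither list passed, with medians of 0.42 (adjusted p = 0.174) and 0.52 (0.0682), and without het 1-cell library 2 alone the medians were 3.80 and 2.04. The oocyte median was 0.69 without het 2-cell library 1. Ribosomal proteins (-0.39, 0.0208) and P-body genes (0.32, 0.0404) also passed and had an adjusted p = 0.956 with an estimated correlation. Without the ceiling libraries, again with het 1-cell library 2 alone in its group, the ribosomal proteins stood at -0.32 and P-body genes at 0.19. No member of the 4 lists was called, over all genes or adjusted over the list alone. Values with the smallest p were Prl8a2 2.88, Mfap2 2.76 and Gstm5 2.83, and on the lower side Abhd18 -2.23, Rrp9 and the cap-binding complex subunit Ncbp1, the last 2 without a value because WT 1-cell embryos held 2 counts of each. Eif4enif1 had a difference of 0.52 (SE 0.58, adjusted p of 1.0). Without the 2 ceiling libraries or without het 1-cell library 3, or with the replicate number as a block, the count was 0, without het 1-cell library 2 it was 143, without WT 2-cell library 3 or het 2-cell library 1 it was 2. The ribosomal protein median was 0.018 (adjusted p = 0.370) without het 2-cell library 1 and -0.73 without het 2-cell library 3, and this list also failed without het 1-cell library 2, WT 1-cell library 3 or WT 2-cell library 1 (0.0925, 0.0990 and 0.155). P-body genes failed without het 1-cell library 3, WT 1-cell library 3, WT 2-cell library 2 or het 2-cell library 1 (0.0919, 0.195, 0.158 and 0.0674) or with RLE scaling (0.0509).

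Arrested embryos were compared with het 1-cell embryos to ask what had changed during culture without cleavage. The 3 arrested libraries were not alike: over genes that rise in WT embryos between the 1-cell stage (0) and the 2-cell stage (1), library 1 stood at -0.0083 and libraries 2 and 3 at 0.671 and 0.626. Of 48 genes specific to the 2-cell stage 39 rose (41 adjusted over the list alone, median 6.17, or 5.91 at the bounds, list adjusted p = 1.42e-28, and 6.77 without arrested library 1), with Gm8300 (8.67). Mitochondrially encoded OXPHOS genes had 10 of 13 up (13 adjusted over the list alone, median 3.71, list adjusted p = 6.28e-19), with mt-Nd3 (3.70) and mt-Nd4l (4.03). Their share of counts was 15.7%, 16.2% and 17.3% in arrested libraries 1, 2 and 3, against 0.44%, 3.68% and 0.34% in het 1-cell libraries 1, 2 and 3, of which 1 and 3 have the count ceiling. Without the ceiling libraries, chosen after seeing the data, the median was 2.35 (adjusted p = 4.64e-15), and without het 1-cell library 2 it was 5.98. Meiotic cell-cycle genes had 12 down and 4 up of 60 (17 and 5 adjusted over the list alone, median -0.57, list adjusted p = 0.0184), with the checkpoint kinase Bub1b (-4.64), Mos (-4.39), the phosphatase Cdc25a (-2.80) and the polo kinase Plk1 (-2.33). Each of these 3 lists had an adjusted p = 0.180 with an estimated correlation. The meiotic list failed without het 1-cell library 2, arrested library 1 or arrested library 3 or with only these 6 libraries in the fit (adjusted p = 0.323, 0.0955, 0.0544 and 0.379), and its median was -0.38 without het 1-cell library 3.

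Ribosomal proteins had 31 of 79 up in arrested over 1-cell embryos (41 adjusted over the list alone, median 1.62), with Rpsa (3.57). Blood markers had 5 of 9 up (7, median 6.83, or 6.71 at the bounds), with Hba-a2 (7.60) and Cd74 (at least 979-fold). Their adjusted p were 2.32e-09 and 0.0192, and adjusted p = 0.861 and 0.674 with an estimated correlation. Without arrested library 2 their medians were 1.02 and 4.35. The blood list failed without het 1-cell library 2 or arrested library 3 (adjusted p = 0.0669 and 0.0504), or with only these 6 libraries (3.94, 0.379). Of 34 p53 and apoptosis genes 10 rose and 1 fell (10 and 2 adjusted over the list alone), with the BCL2-family members Mcl1 (4.25) and Pmaip1 (6.41) and the p53 target Zmat3 (at least 52.2-fold). That list did not pass (adjusted p = 0.341), nor did oocyte genes, with 11 down and 2 up (12 and 2, adjusted p = 0.208). Dnmt1 fell (-3.63).

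Of the arrested over 1-cell increases, Trim43a was largest, at least 2457-fold higher (157 ± 170 CPM, n = 3, against 0 counts), Cited1 at least 1952-fold, Obox6 at least 1733-fold, Zfp352 at least 1236-fold, Crxos at least 1212-fold and Dkkl1 at least 810-fold. The decreases were led by Sbk3 (-6.66), Zfp866 (-6.57), the RNase P subunit Rpp38 (-5.49), Slc35f6 (-5.33) and the centromeric cohesin protector Sgo2b (-4.80). Eif4enif1 stood at -0.07 (adjusted p = 0.935). In total 3283 genes were called, 2358 up and 925 down. With only these 6 libraries in the fit the count was 0, and without the 2 ceiling libraries 104, of which 19 were up. Without het 1-cell 1, 2 or 3 it was 1222, 1787 and 1270, without arrested library 1 it was 5938, and DESeq2 called 5934.

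Arrested embryos, with library 1 again apart from libraries 2 and 3 on the zygotic rise (-0.0083), were also set against het 2-cell embryos cultured for as long. Ribosomal proteins fell in 50 of 79 cases and rose in 0 (77 down adjusted over the list alone, median -2.54, list adjusted p = 3.67e-30), with Fau (-3.40), Rpsa (-2.76) and Rps10 (-2.39). Nucleolar genes had 13 of 48 down (28, median -1.66, 1.21e-10), with Gnl3 (-2.89) and Ebna1bp2 (-2.37). Nuclear-encoded OXPHOS genes had 17 of 78 down (32 down and 2 up, median -1.31, 4.7e-08), with the complex I subunit Ndufs7 (-3.96) and Uqcrq (-3.85), and mitochondrial ribosomal proteins had 18 down and 2 up of 78 (26 and 4, median -1.36, 6.57e-07), with Mrps6 (-3.25). RNA polymerase II and splicing genes had 16 down and 1 up of 52 (25 and 6, median -1.29, 2.02e-05), with the polymerase subunit Polr2k (-3.55) and the spliceosomal Sf3b6 (-3.32). Translation initiation genes had 10 down and 2 up of 43 (15 and 2, median -0.90, 0.00455), with the cap-binding Eif4e3 at 2.63. Without arrested library 1 the medians were -2.14 (ribosomal proteins), -1.40 (nucleolus), -1.27 (nuclear-encoded OXPHOS), -1.10 (mitochondrial ribosomal proteins), -1.29 (RNA polymerase II) and -0.79 (translation initiation), and all 6 lists passed. Translation initiation failed without arrested library 3 (adjusted p = 0.0675) and had -1.66 without arrested library 2.

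Against 2-cell embryos, oocyte genes had 9 of 47 up and 0 down in arrested embryos (18 up and 3 down adjusted over the list alone, median 1.16, list adjusted p = 1.04e-06), with Nlrp4a (3.51) and the oocyte transcription factor Sohlh2 (6.72). P-body genes had 7 of 50 up (9 adjusted over the list alone, median 0.61, adjusted p = 0.0119), with the deadenylase subunits Cnot6l (2.47) and Cnot4 (2.76) and the germ-cell RNA-binding protein Dazl (3.01). The APC/C inhibitor Fbxo43 (3.83) and the dioxygenase Tet3 (2.12) rose, and the autophagy gene Map1lc3b fell (-3.02). The 2-cell-stage list lay at a median of -1.19 (adjusted p = 7.09e-05) with 1 of 48 called, lower (0 adjusted over the list alone). Mitochondrially encoded OXPHOS genes had 0 of 13 called in edgeR at a median of 0.21 (adjusted p = 0.332). With an estimated correlation the adjusted p = 0.545 for 2-cell-stage genes and 0.371 for the other 8 lists that passed. Without arrested library 1 P-body genes did not pass (median 0.37, adjusted p = 0.120) and the oocyte and 2-cell-stage medians were 0.82 and -0.74, both still passing. The 2-cell-stage median was -1.85 without arrested library 2.

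The largest increases in arrested over 2-cell embryos were Zfp735 (5.70), Cd300c (5.26), Rfpl4 (140 ± 99.4 to 4440 ± 3613 CPM, log2 4.99, n = 3), Med30 (4.82), H1foo (63.8 ± 36.9 to 1572 ± 1170 CPM, log2 4.62) and Obox1 (4.59). The largest decreases were the protease Capn11 (-7.57), the mitochondrial transcription elongation factor Tefm (-6.97), Zfp977 (-5.95), Rpp38 (-5.72), Fbxo6 (-5.64) and the nucleolar Nop53 (-5.60), and Eif4enif1 stood at 0.56 (adjusted p = 0.406). In total 1986 genes were called, 910 up and 1076 down. With only these 6 libraries in the fit the count was 0, without het 2-cell 1, 2 or 3 it was 3114, 4 and 2, without arrested 1 or 2 it was 1127 and 4004, and DESeq2 called 5075. Without the expression filter 33.5% of calls were up against 45.8%.

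Het libraries were placed between the WT 1-cell mean (0) and the WT 2-cell mean (1). Over 6816 genes that rise in WT embryos the positions averaged 0.066 ± 0.029 in het 1-cell and 0.910 ± 0.046 in het 2-cell embryos (n = 3), and arrested libraries 1, 2 and 3 stood at -0.0083, 0.671 and 0.626. Over 3357 genes that fall, the means were 0.097 ± 0.038 and 0.874 ± 0.182, and the arrested libraries stood at 0.314, 0.781 and 0.453. Exact two-sided permutation p (n = 3 per group) were 0.1 for 1-cell against 2-cell on both lists, 0.4 and 0.1 for 1-cell against arrested, and 0.1 and 0.2 for arrested against 2-cell, on the rising and falling lists. Adjusted over these 6 tests the values were 0.15, 0.4, 0.15, 0.15 and 0.24, and 3 libraries against 3 cannot go below 0.1.

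**Figure D5:**
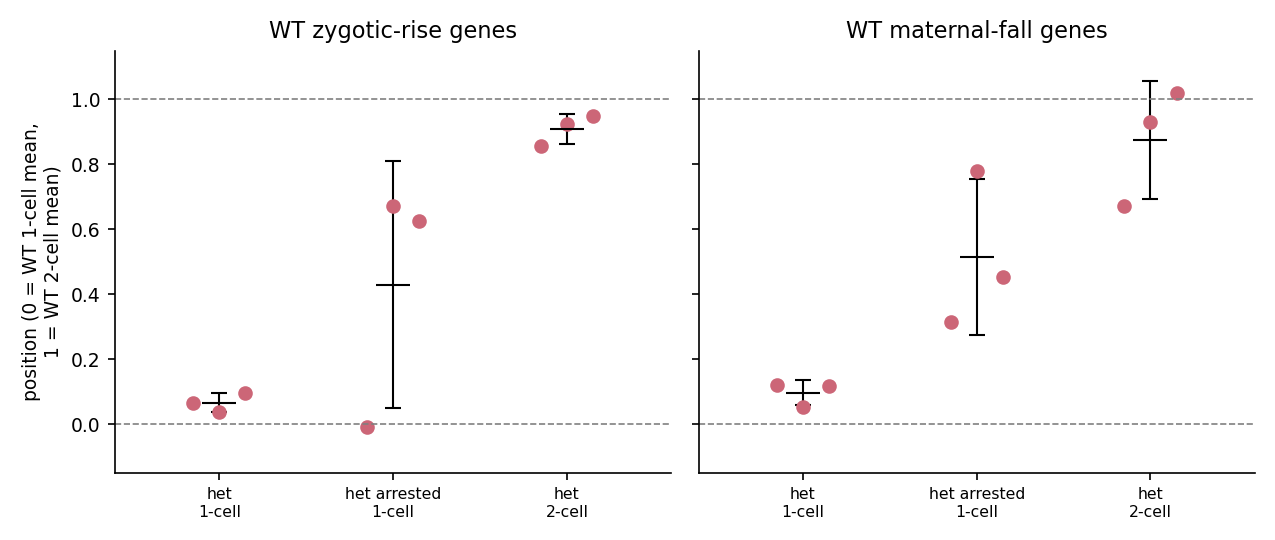
Position of each het embryo library (vertical axis, 0 at the WT 1-cell mean and 1 at the WT 2-cell mean, dashed lines) over genes that rise (left, 6816 genes) and fall (right, 3357 genes) in WT embryos, by group (horizontal axis). Points are libraries, bars means and whiskers 1 SD; arrested libraries spread from -0.0083 to 0.671 on the left and from 0.314 to 0.781 on the right.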

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

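Tests chosen only after the result was seen were the scaling test, the within-group comparison of granulosa markers with mitochondrial share, the mitochondrial share in 2-cell embryos, the mitochondrially encoded list without the ceiling libraries, the depth test of those libraries, the mitochondrial share of arrested library 1, and the fits without the ceiling libraries. For 3 genes the genotype difference itself differed between the fractions of GV oocytes by an interaction test: Mycl (-3.77), Mtfr2 (-2.65) and Gm21887 (3.52). For Btg1-ps1 the het minus WT difference of the 2-cell versus 1-cell change was at least 6.54 on the log2 scale, a bound at the floor of 3 counts, with 0 counts in every WT 2-cell library and 30, 64 and 47 in the het ones.

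Mitochondrially encoded, ribosomal protein and granulosa-marker mRNAs were higher together in het GV translatomes, with median log2 changes of 2.12, 0.86 and 1.03. Ribosomal protein and mitochondrially encoded medians lay at percentile 100 of 10000 random lists matched on exon length and expression (random medians 0.12 and 0.31). Exon length alone falls short, and mRNA length was untested. Scaling moves all genes alike, and the mitochondrially encoded median lay 2.09 above that of all genes. The gap restates the shift, and the test cannot decide. RNA from granulosa cells is a candidate source that stays open, since the library with more granulosa-marker RNA also had the higher mitochondrial share in 2 of the 4 GV groups and the higher ribosomal protein level in 1 of the 4, the WT translatome (7775 against 5293 CPM), and with 2 libraries per group neither count decides. Of the 23 granulosa genes tested, 11 reached 1 CPM in the WT transcriptome, 0 are on another list, and the most abundant were Serpine2 (555 ± 64.1 CPM in het and 429 ± 57.7 CPM in WT translatomes, 341 ± 80 and 347 ± 108 CPM in transcriptomes), Inha (598 ± 203 and 178 ± 124, 191 ± 64.5 and 68.3 ± 48.7 CPM) and Cyp19a1, whose het means were the lower in both (26.8 ± 2.95 and 33.5 ± 6.73, 29.9 ± 5.18 and 44.2 ± 5.04 CPM); the labels name no step that removes such cells. An effect of genotype, the biological explanation that the design gives, also stays open, with a higher mitochondrial share in het 2-cell embryos at an exact p of 0.1, the smallest that 3 against 3 allows.

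In het 1-cell embryos the oocyte and mitochondrially encoded lists had medians of -0.87 and -0.98, with 2 of the 3 libraries showing a count ceiling. Depth does not account for the ceiling, as the level exceeded by 0.1% of genes (in counts per kb per M counts) was at most 0.234 times the lowest WT 1-cell value. The ceiling may be the source of both shifts, since without those libraries the medians were 0.154 and 0.252. What made the ceiling was not tested, and removal of duplicate reads in these libraries alone may be one candidate. A genotype effect on these lists stays open and untested beyond het library 2, the only het 1-cell library without the ceiling.

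Arrested library 1 stood at -0.0083 on the zygotic-rise axis, near 1-cell embryos, and libraries 2 and 3 at 0.671 and 0.626. A 1-cell embryo labelled as arrested is argued against by its mitochondrial share of 15.7%, against 3.68% in the highest 1-cell library. Depth did not set library 1 apart (16.71 M against 19.16 M and 16.06 M), so thinning to 5597333 counts (0.011 against 0.694 and 0.609) was no test. Library 1 had fewer genes detected (18025 against 20593 and 25230). RNA quality was not tested, nor was a biological cause such as arrest before or after genome activation.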

How the results depend on the processing

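Chosen only after the data were seen were the fits without the 2 het 1-cell libraries with a count ceiling and the fits without arrested embryos; the other alternatives were planned. Median-ratio scaling, leaving mitochondrially encoded genes out of the scaling and a fold-change minimum kept every count of calls in the 11 comparisons within 1.5 times, and no gene list passed in the opposite direction under median-ratio scaling. Among named genes, 2811 results with 1 library left out stayed on their side of the threshold, 523 lost the call and 12 gained it, and DESeq2 kept 573, lost 2 and gained 17. Where a value moved, the cause was not tested unless stated.

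Without the expression filter more low-count genes were tested, and calls rose from 1034 to 2113 in the GV translatome, from 572 to 1554 in the transcriptome, from 3 to 108 for the difference between fractions and from 1 to 2 in 2-cell embryos. DESeq2 called 1860, 1423 and 112 genes in those GV comparisons, 83 in 1-cell embryos (edgeR 0), 140 in 2-cell embryos, 79 for the het minus WT difference of the transition, 5934 for arrested versus 1-cell and 5075 for arrested versus 2-cell embryos. With only the compared libraries in the fit, which leaves fewer to estimate the spread, calls were 1570 for the WT fractions, 0 for 2-cell embryos, 3 for the het minus WT difference, and 0 for both arrested comparisons, and Eif4enif1 in the translatome stood at -1.26 with an adjusted p of 0.0512. In that fit 68.7% of transcriptome calls were up against 55.4%.

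The replicate number as a block gave 670 calls in the GV translatome, 414 in the transcriptome, 0 for the difference between fractions, 2621 for the WT fractions, 0 for the het minus WT difference of the transition, 1909 for arrested versus 1-cell and 1331 for arrested versus 2-cell embryos, with fewer residual degrees of freedom. Across genotypes or stages the labels give no pairing by that number, and deviations of same-numbered libraries correlated between -0.443 and 0.258. The oocyte sample as a replicate block, which does pair the fractions, gave 7 calls for the difference between fractions and 3898 for the WT fractions, and changed no other call of a named gene or list.

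Without the ceiling libraries, calls were 2017 for the het transition, 0 for the het minus WT difference and 104 for arrested versus 1-cell embryos, and 42.4% of het transition calls were up against 62.1%. In the 1-cell comparison the list test then turned upward for 3 lists, with medians of -0.0029 for nuclear-encoded OXPHOS (median and test differing in sign), 0.252 for mitochondrially encoded OXPHOS and 0.154 for oocyte genes. Without arrested embryos the 2-cell count was 4 and that of the het minus WT difference 3.

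With an estimated inter-gene correlation 0 lists passed in any of the 11 comparisons, where the preset correlation passed 9, 6, 7, 8, 6, 6, 10, 10, 4, 5 and 9. With only the compared libraries 3 lists passed in 1-cell embryos and 3 for arrested versus 1-cell embryos, and without the ceiling libraries 1 passed in 1-cell embryos, 1 for the het minus WT difference and 11 for arrested versus 1-cell embryos. Without het 2-cell replicate 1 the medians of ribosomal proteins (0.287, adjusted p = 0.00239) and nucleolus genes (0.0471, 0.897) in 2-cell embryos and of ribosomal proteins in the het minus WT difference (0.0181, 0.370) had the opposite sign. With each library left out in turn these medians ran from -0.491 to 0.287, -0.430 to 0.0471 and -0.728 to 0.0181.

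Leaving out each library in turn, calls ran from 154 to 1056 in the GV translatome, 69 to 644 in the transcriptome, 0 to 10 for the difference between fractions, 1195 to 2198 for the WT fractions, 0 to 284 in 1-cell and 1 to 2 in 2-cell embryos, 7971 to 9023 for the WT and 5861 to 8250 for the het transition, 0 to 143 for their difference, 1222 to 5938 for arrested versus 1-cell and 2 to 4004 for arrested versus 2-cell embryos. The lowest of these came without het translatome 1 (154), het transcriptome 2 (69), WT transcriptome 1 (1195), het 1-cell 1 (1222) and het 2-cell 3 (2), and the highest without het 1-cell 2 (284 and 143), arrested 1 (5938) and arrested 2 (4004). Eif4enif1 ran from -1.53 to -0.95 in the translatome and from -1.29 to -1.18 in the transcriptome. The number of lists passing ran from 8 to 8, 7 to 8, 5 to 7, 5 to 10, 4 to 8, 2 to 10, 7 to 9, 7 to 11, 2 to 5, 3 to 6 and 8 to 10 in the order above, with 2 in 2-cell embryos without WT 2-cell 1.

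On the stage axis, het 1-cell embryos stood at 0.0992 over rising and 0.0291 over falling genes with the median in place of the mean, and at 0.0493 over falling genes without the ceiling libraries. Depth limits the het 1-cell and het transcriptome groups most, with 5.6 M and 3.62 M counts in their shallowest libraries. In simulated 1-cell embryos edgeR recovered 0% of 4-fold changes, so its 0 calls there exclude no change of that size.

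For each comparison of 3 libraries against 3, the 10 splits of the 6 libraries are too few for a share under 0.05. As many calls as the real split came from 10 splits in 1-cell embryos (0 real, 0 highest other), 3 in 2-cell embryos (1 and 1), and 1, the real split itself, for the WT transition (10981 and 0), the het transition (8693 and 0), arrested versus 1-cell (3283 and 1033) and arrested versus 2-cell embryos (1986 and 146). For the het minus WT difference 5 of 40 drawn splits of genotype within stage gave as many calls (1 real, 1 highest other), so chance is not excluded.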

Other observations

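The hypotheses in this part had predictions set before their results were seen, except for the translatome call rate near Eif4enif1. Between the 1-cell and 2-cell stages of WT embryos, where 46.4% of all genes tested were called, 3 lists that did not pass held called genes too. Among meiotic and cell-cycle genes 13 rose and 13 fell of 60 (13 and 13 adjusted over the list alone): the S-phase cyclin gene Ccne1 (15.6 ± 2.06 to 511 ± 121 CPM, log2 5.04, n = 3) and Cdk4 (4.22) rose, while the replication licensing gene Mcm2 (-2.83) and the APC/C inhibitor Fbxo43 (-3.75) fell. Mitophagy and autophagy genes had 9 up and 4 down of 30 (9 and 4 adjusted over the list alone), with the ATG8-family members Gabarap (7.51) and Map1lc3a (6.51) and the lysosomal membrane gene Lamp2 (21.4 ± 4.22 to 482 ± 120 CPM). Fusion and fission genes had 8 up and 9 down of 30 (9 and 10 adjusted over the list alone), with the fission GTPase Dnm1l at -2.38. The list adjusted p were 0.333, 0.186 and 0.385.

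In arrested versus 1-cell het embryos, splicing factors Prpf6 (-2.65), Sf3b3 (-3.26), Sf3b4 (-2.70) and Sf3a3 (-2.58) fell, within a list of RNA polymerase II and splicing genes that had 5 up and 8 down of 52 (9 and 12 adjusted over the list alone, adjusted p = 0.341).

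As a hypothesis, strain variants carried with the mutant allele could raise the call rate near Eif4enif1. Within 10 Mb of the gene 7 of 120 genes were called in the GV transcriptome, against 563 of 22260 elsewhere, a rate ratio of 2.31 (Fisher's exact p = 0.0340, two-sided), and in the translatome 11 of 120 against 1021 of 22260, a ratio of 2.00 (p = 0.0263). The transcriptome ratio was as predicted. No prediction was set for the translatome, whose ratio before rounding was 1.999. Calls clustered among neighbours, so both p may be too small. Regulation by genotype there was not excluded.

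A further hypothesis was that neighbouring genes share reads or local transcription. In the het versus WT transcriptome 44 neighbouring pairs were called in the same direction, 5.97 times the mean of 7.38 over 10000 random relabellings of the calls (highest 18, permutation p = 1e-04, the smallest these relabellings can give). Pairs such as Muc4 with Muc20, Malat1 with Gm37376, Gpx7 with Tut4 and Mt1 with Mt2 were among them, so some calls may not be separate events, and shared reads and local regulation cannot be told apart from counts alone.

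Gene length may set part of the difference between fractions in WT oocytes, as a further hypothesis. Across 22381 genes the log2 translatome over transcriptome difference had a Spearman correlation of 0.357 with exon length, against -0.166 for het versus WT in the translatome and 0.0637 in the transcriptome, with genes not being independent replicates. The lower translatome levels of the short ribosomal protein and OXPHOS mRNAs in WT oocytes are in line with this, and capture by length was not separated from ribosome loading by length.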
